A study of Mus musculus with 4 samples.

How the data were processed

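Cells of whole neonatal mouse testes, with no selection by marker or sort, were profiled by 3' single-cell RNA sequencing (10x Genomics) in 4 libraries: 2 from pups injected with DMSO, the solvent, and 2 from pups injected with 100 µg of all-trans retinoic acid (RA), the active form of vitamin A. Per the labels, testes were taken 12 h after the single subcutaneous injection, at 1.5 days of age, digested with trypsin and EDTA, and loaded at 17400 cells per library. Each suspension pooled the testes of at least 2 pups, and litters were pooled separately for each replicate experiment, so the replicate is a pool of pups. The labels number the replicates 1 and 2 in each group but do not say that a DMSO and an RA library of the same number share a litter, so libraries were not paired in the tests reported.

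The files hold UMI counts per gene and cell barcode, as deposited by the authors. The submitters' processing notes name Cell Ranger, bcl2fastq and FastQC and the builds mm10 and GRCm38; their versions and the gene annotation are not given in the sources used here. Every barcode of the 4 single-library matrices was read, and their numbers (7234, 8183, 9728 and 9008 for DMSO 1, DMSO 2, RA 1 and RA 2) equal the cell numbers stated in the labels. A further deposited matrix holds the 4 libraries pooled by the authors, with 298407171 of the 312009122 UMI counts of the single matrices (95.6%); it was used for that total alone. Of 27998 gene identifiers, 27645 (98.7%) were found in the GENCODE annotation of GRCm38 used for positions.

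Sequencing gave 68289008, 72517149, 90472182 and 80730783 UMIs in DMSO 1, DMSO 2, RA 1 and RA 2, with medians of 8471, 8237, 8172 and 8057 UMIs and 2519, 2450, 2594 and 2473 genes per barcode. Barcodes with fewer than 500 genes (58, 74, 39 and 70) or more than 10% of UMIs from mitochondrial genes (313, 319, 332 and 384) were left out. Doublets were scored with Scrublet (scanpy 1.11.5), and the highest-scoring share of 0.8% per 1000 barcodes was removed (397, 510, 728 and 617), which left 6470, 7284, 8631 and 7938 cells, 30323 in all. The 4 libraries were not copies of one another: the chi-square over genes divided by its degrees of freedom was 20.7 between the DMSO libraries and 50.1 between the RA libraries, where sampling noise gives about 1.

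Cells were normalized to 10000 UMIs, and 2000 variable genes chosen within library were reduced to 30 principal components; 137 genes of the mitochondrial, haemoglobin, retinoid response, cell cycle and immediate early groups were kept out. A graph of 15 neighbours was split by Leiden clustering (leidenalg 0.10.2, resolution 1). A cluster took the name of 1 of 13 classes where at least 3 of that class's markers were detected in 10% of its cells and its top 10 genes by fold held no more markers of another class than of its own. Because clusters of dividing Sertoli cells were first named erythroid through haemoglobin RNA spread over all cells, a marker among the top 10 genes was then required for the erythroid class alone, and for all classes folds were taken within libraries with 10 CPM (UMI counts scaled to a common library total) added; this part of the rule was written after the data were examined. Classes with at least 20 cells in each library were tested.

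UMI counts were summed per library over the cells of a class and tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, quasi-likelihood F test, 2-sided, Benjamini-Hochberg adjusted p under 0.05). The same model on cell numbers, with the number of kept cells as offset, tested class shares. A class by treatment term, with library as block, tested whether germ and Sertoli cells responded differently. Germ cells with and without a Stra8 UMI were compared within the RA libraries after thinning each cell to 2000 UMIs, with Stra8 left out. Gene lists (20, fixed in advance, with at least 3 tested members) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a class, and again with the correlation estimated from the residuals. Of 152 list tests over 8 sets of cells, 45 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.129), where residuals come from 2 libraries per group; fry, which tests whether a list's genes move on balance one way, passed 8. In the 45 lists the median, the mean and the test had the same sign. Permutation tests were exact and 2-sided; with 2 libraries per group the smallest p they can give is 0.333. Levels are in CPM of the summed counts with TMM-scaled library sizes, as mean ± SD of 2 libraries, and fold changes are fitted log2 values ± SE. For a count of 0 a floor of 3 UMIs over the group was used, and 1 to 3 UMIs give a ratio with an exact counting interval; fitted fold changes of such genes depend on the prior count and bound nothing. Intervals and floors cover counting error alone, not the spread between pools of pups.

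The genes named were set by rule: in germ and Sertoli cells the 8 with the largest rise and the 8 with the largest fall past the threshold, with a mean of 10 CPM or more and both RA libraries on the same side of both DMSO libraries; 3 and 3 elsewhere; 5 and 5 for the class by treatment term and for cells with against without Stra8; up to 4 members of each list by smallest p; and a fixed set of genes given whatever their p. Some genes that the rule names are not reported here. The comparisons, lists, markers, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, no TMM scaling, no gene filter, a filter at 10 CPM, a replicate block, no doublet removal, all barcodes as deposited, Leiden resolution 2, classes assigned cell by cell from at least 2 marker UMIs, other thinning depths (1000 and 4000 UMIs, and none) and leaving out each library. The subtraction of free RNA (RNA from other cells in a droplet) was added after the data were examined. Its share was estimated per class and library from Sertoli and stromal markers of at least 100 CPM in the whole library, as their level in the class over that in the library.

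The edgeR test was tested on counts drawn from a negative binomial model with the mean levels, library sizes and trended dispersion of each class. In the RA libraries the means of 200 genes were changed 1.5-fold, 2-fold or 4-fold, up or down. Recovery therefore holds for a spread that follows this trend. In germ cells (10509 genes tested) it recovered 17.9% of 1.5-fold, 46.3% of 2-fold and 84.8% of 4-fold changes; in Sertoli cells (13471 genes) 29.9%, 85.1% and 97.0%; in stromal cells (13082 genes) 31.3%, 80.6% and 95.5%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Reads were not analysed here.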

Results

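Testis cells of mice at 1.5 days of age were measured 12 h after an injection of DMSO or of 100 µg RA, in 2 libraries per group. At this age the seminiferous cords hold germ cells and Sertoli cells, the somatic cells that nurse them, and peritubular myoid, stromal, Leydig and vascular cells lie around the cords. After filtering, 6470 and 7284 DMSO cells and 8631 and 7938 RA cells were kept, from libraries with medians of 8057 to 8471 UMIs per barcode.

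Sertoli cells made up 40.9 and 44.7% of the cells in the DMSO libraries and 35.2 and 41.5% in the RA libraries, and interstitial stromal cells 39.6 and 36.0% against 44.2 and 39.3%. Peritubular myoid cells, the contractile layer around the cords, held 14.7 and 15.2% against 15.9 and 15.2%. By markers the mean myoid share was 6.75% after DMSO and 12.8% after RA (log2 change 0.92, adjusted p = 0.0838). Acta2, Myh11 and Lmod1, markers of this assignment, themselves rose in myoid cells after RA (below). The share by markers can therefore rise without a change in cell number. Germ cells were 87 of 6470 and 69 of 7284 cells after DMSO and 162 of 8631 and 90 of 7938 after RA. These shares of 1.35, 0.947, 1.88 and 1.13% gave a log2 change of 0.40 ± 0.35 (adjusted p = 0.673; exact permutation p = 0.667). No class share passed the edgeR test among 12 classes. Erythroid cells (9 and 20 cells after DMSO, 0 and 3 after RA; unadjusted p = 0.00503, adjusted p = 0.0604) and other immune cells (unadjusted p = 0.0389) were the 2 with an unadjusted p under 0.05. The erythroid adjusted p was 0.0154 without RA replicate 2, 0.0152 with no doublets removed and 0.00379 at resolution 2. With barcodes as deposited the erythroid class held 61, 89, 37 and 69 cells in DMSO 1, DMSO 2, RA 1 and RA 2, and its log2 change was -0.75 (adjusted p = 0.186) against -3.42 after filtering.

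Clusters separated by treatment in the main somatic classes although retinoid response genes had been kept out of the clustering. In Sertoli cells 10 of 11 clusters, with 96.7% of the cells, held at least 90% of their cells from one group: clusters 1, 9, 10, 14 and 16 from RA and clusters 2, 11, 13, 15 and 18 from DMSO. In stromal cells 4 of 7 clusters (85.3% of cells; 0 and 6 from RA, 3 and 5 from DMSO) and in myoid cells 2 of 4 (79.4%; 4 from RA, 7 from DMSO) did so. None of the germ, Leydig, endothelial and macrophage clusters did. The sums per class take these clusters together.

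The central comparison asked what RA changed in germ cells, the classical responders to it. Stra8, the retinoid-induced gene needed for entry into meiosis, rose from 30.4 ± 20.9 CPM after DMSO to 126 ± 29.1 CPM after RA (mean ± SD of 2 libraries; log2 change 2.19 ± 0.27, adjusted p = 6.29e-05). Its log2 change was 1.50 without DMSO replicate 1 and 3.03 without DMSO replicate 2, and passed in both. Hoxb4, a homeobox gene of the retinoid-responsive Hox clusters, rose from 15.9 ± 3.08 to 64.8 ± 4.88 CPM (2.05 ± 0.25, adjusted p = 6.29e-05). Rarb, which encodes a retinoic acid receptor, rose from 5.27 ± 1.78 to 29.9 ± 2.7 CPM (2.44 ± 0.36, adjusted p = 7.42e-04). Sall4, a zinc finger factor of spermatogonia, rose from 86.7 ± 3.62 to 204 ± 48.4 CPM (1.25 ± 0.18, adjusted p = 5.55e-04). The retinoid-degrading enzymes rose too: Cyp26b1 from 5.44 ± 0.61 to 25.6 ± 10.5 CPM (2.12 ± 0.41, adjusted p = 0.0148), and Cyp26a1 from 1 UMI in both DMSO libraries together to 65 in both RA libraries. This is a ratio of 41.4 with a counting interval of 7.17 to 1660 (adjusted p = 5.58e-04). Of 10509 genes tested, 15 rose and 7 fell, with 923 at an unadjusted p under 0.05. The median log2 change of all germ cell genes was -0.003 with TMM scaling and 0.107 without it. The other rises named by the rule were Fstl3 (2.54 ± 0.48), Cidea (2.11 ± 0.32) and Id3 (1.40 ± 0.28), at 18.0, 38.7 and 40.5 CPM after RA. The falls were Rhox8 (-1.79), Wfdc10 (-1.64), Clu (-1.23), Gstm2 (-1.07), Insig1 (-0.89 ± 0.16, from 157 to 85.2 CPM) and Rps28 (-0.61 ± 0.11, from 9194 to 6016 CPM). Rhox8, Wfdc10, Clu and Gstm2 stood at 24.0, 23.9, 84.3 and 68.9 CPM in germ cells after DMSO and at 1183, 312, 1546 and 1778 CPM in Sertoli cells, where they fell as well. Fstl3, Cidea and Id3 rose in the sum over all cells (log2 3.47, 4.79 and 1.17).

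RNA from other cells made up an estimated 6.23 and 5.50% of germ cell UMIs after DMSO and 7.72 and 7.19% after RA, and with it subtracted 7 of the 22 genes passed: Hoxb4, Stra8, Sall4, Rarb, Cyp26a1, Insig1 and Rps28. Of the others, 6 were below the gene filter after the subtraction, Fstl3, Id3 and Rhox8 among them, Cidea went from 2.11 ± 0.32 to 0.16 ± 0.51, Cyp26b1 from 2.12 ± 0.41 to 1.80 ± 0.60, and Gstm2 from -1.07 ± 0.20 to -2.35 ± 0.62. Cpm (1.08 ± 0.23 to 1.10 ± 0.23, adjusted p = 0.13) and 2810474O19Rik (0.90 ± 0.17 to 0.88 ± 0.18, adjusted p = 0.0821), named after their values were seen, lost the call with fold and SE nearly unchanged. Leaving out 1 library gave 55 genes (DMSO replicate 1), 106 (DMSO replicate 2), 9 (RA replicate 1) and 55 (RA replicate 2). The excess of rises was not kept throughout: 25 rose and 30 fell without DMSO replicate 1, 18 and 37 without RA replicate 2 and 20 and 23 by markers. Among the named germ cell genes that passed, Hoxb4 alone passed in the same direction under every alternative. Without RA replicate 1 the adjusted p was 0.635 for Fstl3, 0.0884 for Id3, 0.0569 for Sall4, 0.0755 for Rhox8, 0.1 for Wfdc10, 0.0686 for Clu, 0.488 for Gstm2 and 0.401 for Insig1. It was 0.0695 for Cyp26b1 without RA replicate 2, 0.26 for Wfdc10 and 0.102 for Clu without DMSO replicate 1, and 0.0756 for Rps28 without DMSO replicate 2. DESeq2 passed 4 genes, all higher after RA, and gave Stra8 a log2 change of 2.07 with an adjusted p = 1. The adjusted p was 0.0647 for Rarb, 0.322 for Cyp26a1, 0.378 for Cyp26b1, 0.475 for Fstl3 and 0.511 for Id3, and none of the falls passed (0.0731 for Rps28, 0.103 for Insig1, 0.13 for Clu). With no doublets removed it was 0.122 for Id3 and Gstm2 and 0.063 for Wfdc10 and Clu.

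Stra8 (ENSMUSG00000029848) lies on chromosome 6, 34920163 to 34939344, plus strand, and Hoxb4 (ENSMUSG00000038692) on chromosome 11, 96318267 to 96321638, plus strand. Rarb (ENSMUSG00000017491) lies on chromosome 14, 16430839 to 16819156, minus strand, and Sall4 (ENSMUSG00000027547) on chromosome 2, 168748332 to 168767943, minus strand. Cyp26a1 (ENSMUSG00000024987) lies on chromosome 19, 37697798 to 37701536, plus strand. Cyp26b1 (ENSMUSG00000063415) lies on chromosome 6, 84571414 to 84593908, minus strand, and Dhrs3 (ENSMUSG00000066026) on chromosome 4, 144892827 to 144928209, plus strand. All are protein-coding genes and all positions are on GRCm38.

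**Figure D1:**
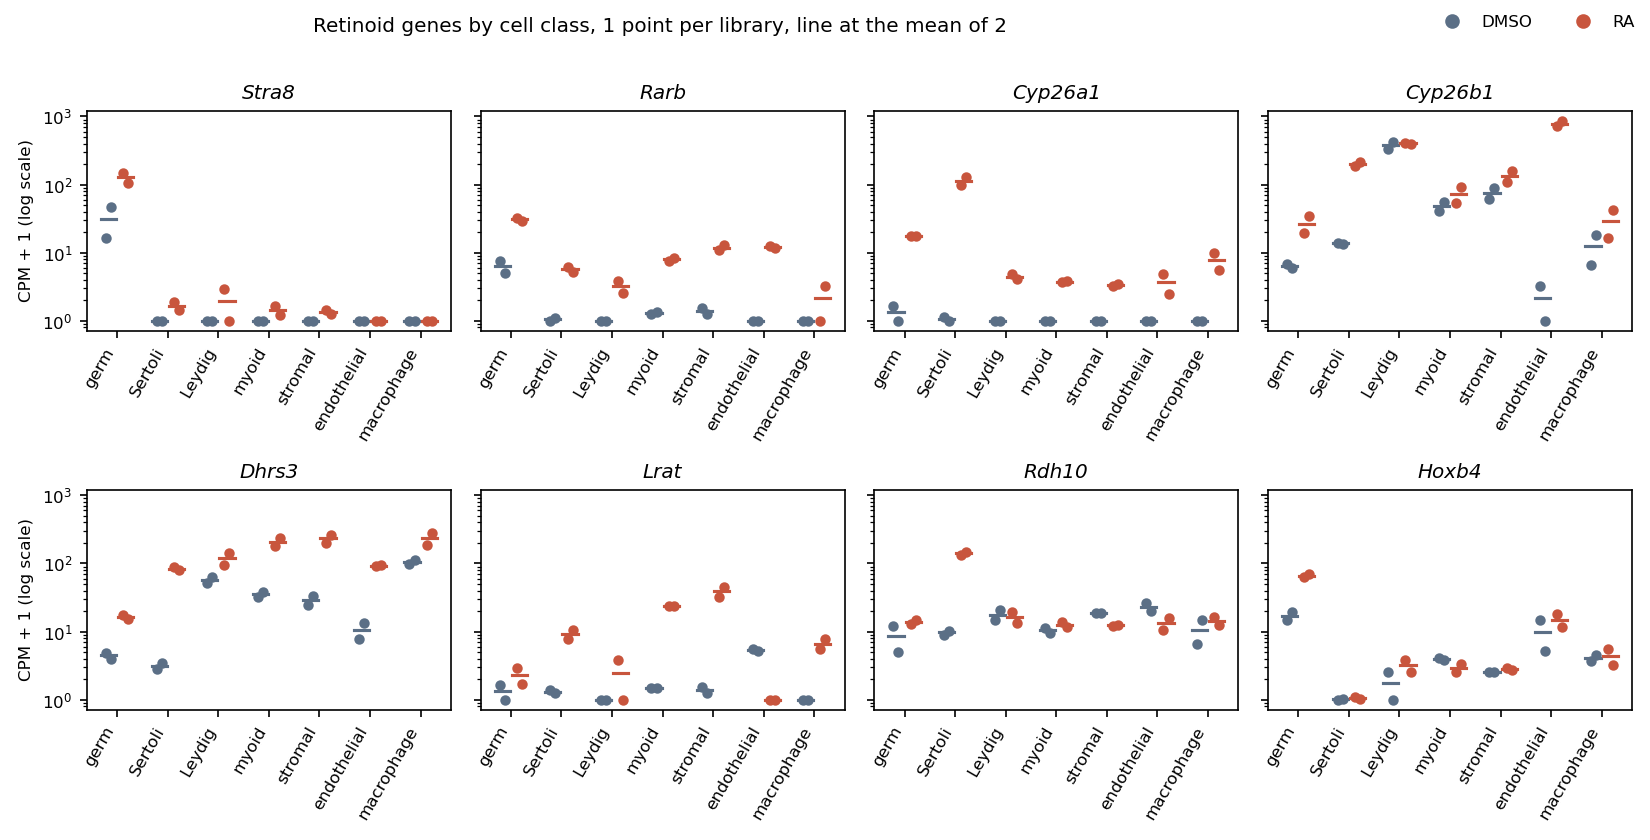
Level (CPM plus 1, log axis) of 8 retinoid-related genes in 7 cell classes; each point is 1 library (DMSO or RA) and each line the mean of 2. Stra8 stands at 15.7 and 45.2 CPM in germ cells of the DMSO libraries and at 147 and 106 CPM in those of the RA libraries, while Dhrs3 in Sertoli cells goes from a mean of 2.11 to 82.8 CPM.

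Among the lists, 5 of 22 retinoid response genes rose in germ cells (Hoxb4, Stra8, Cyp26a1, Rarb and Cyp26b1) and none fell. Of the same list 7 rose when adjusted over the list alone (camera adjusted p = 2.35e-13, adjusted p = 0.593 with an estimated correlation). Of 12 genes of retinoid synthesis and turnover 2 rose, the 2 Cyp26 enzymes (3 adjusted over the list alone, camera adjusted p = 0.00245, adjusted p = 0.593 with an estimated correlation). Of 14 genes of spermatogonial differentiation Stra8 and Sall4 rose (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.206). Stra8 alone rose among 21 genes of meiotic prophase (0.206). No member passed among 23 genes of undifferentiated spermatogonia (1 rose and 1 fell adjusted over the list alone; 0.972), 14 of pluripotency (0.206) and 20 of DNA methylation and transposon silencing (0.201). No member of the S phase list passed (0 of 26), while camera placed the list higher after RA (adjusted p = 0.0129; adjusted p = 0.593 with an estimated correlation). None of 26 genes of G2 and M phase passed. None of 21 collagen and matrix genes passed (camera adjusted p = 0.0468, higher, adjusted p = 0.697 with an estimated correlation). Insig1 fell among 20 cholesterol synthesis genes (0.0603) and Clu among 14 Sertoli identity genes (0.206). None of 6 erythrocyte transcripts passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 1.9e-04, lower, adjusted p = 0.593 with an estimated correlation). Haemoglobin RNA over all cells was 2133 and 3051 CPM in the DMSO libraries and 97.5 and 846 CPM in the RA libraries.

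The germ cell genes fixed for reporting, other than those above, did not pass. Dhrs3, a retinaldehyde reductase, stood at 3.46 CPM after DMSO and 15.3 CPM after RA (log2 change 2.10, adjusted p = 0.0519). It passed in the same direction with no filter (0.00341), without TMM scaling (0.0139), at 10 CPM (0.048) and with no doublets removed (0.00838). It did so too as deposited (0.00824), at resolution 2 (0.0364) and by markers (2.63e-05). Leaving out each library gave log2 changes of 1.97 to 2.34. Over all cells Dhrs3 went from 13.5 and 16.4 CPM after DMSO to 135 and 154 CPM after RA. With free RNA at 7.72 and 7.19% of germ cell UMIs after RA, a rise of this size over all cells raises the germ cell level as well. The part of free RNA in the germ cell change of Dhrs3 was not computed. The settings in which Dhrs3 passed therefore do not show a response of the germ cells themselves. For genes of differentiating spermatogonia, the log2 changes were 0.53 for Ccnd2 (adjusted p = 0.375), 0.47 for Rec8, -0.20 for Kit, -0.16 for Sohlh1 and -0.02 for Dnmt3b. For genes of undifferentiated spermatogonia and self-renewal they were 0.79 for Gfra1 (adjusted p = 0.433), 0.36 for Etv5, 0.30 for Ret and 0.23 for Id4, with Zbtb16 at 10.9 and 18.5 CPM and Pou5f1 at -0.09. Nanos2 had 1 UMI in each group and was not tested. Without DMSO replicate 2, Ccnd2 (adjusted p = 1.32e-05) and Gfra1 (adjusted p = 0.0284) passed. Ccnd2 also passed without TMM scaling (0.0491) and with no filter (0.0454). In simulated data the test recovered 46.3% of 2-fold changes in germ cells, so a change of that size was not reliably detectable at this depth.

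The share of germ cells with a Stra8 transcript was compared at equal depth. After thinning every cell to 2000 UMIs, 3 of 87 (3.45%, exact 95% interval 0.717 to 9.75%) and 5 of 69 (7.25%, 2.40 to 16.1%) germ cells of the DMSO libraries held a Stra8 UMI. In the RA libraries they were 36 of 162 (22.2%, 16.1 to 29.4%) and 14 of 90 (15.6%, 8.77 to 24.7%). The means were 5.35 ± 2.69% and 18.9 ± 4.71%, a difference of 13.5 points (exact permutation p = 0.333, the smallest 2 against 2 libraries can give). With no doublets removed the shares were 8.33 and 13.2% in the DMSO and 25.3 and 16.8% in the RA libraries, a difference of 10.3 points. Each thinned share rests on a single random draw, which the intervals do not cover. Differences between settings may therefore come from the draw. In Sertoli cells, a somatic class in which Stra8 is not normally expressed, the thinned shares were 0 of 2643, 0 of 3254, 5 of 3041 (0.164%) and 4 of 3295 (0.121%). Without thinning the germ cell shares were 23.0, 29.0, 56.8 and 46.7%, at median depths of 20027, 16889, 14697 and 16470 UMIs. The Sertoli shares were 0, 0, 0.987 and 0.486%, at 11071, 10096, 10586 and 10380 UMIs.

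**Figure D2:**
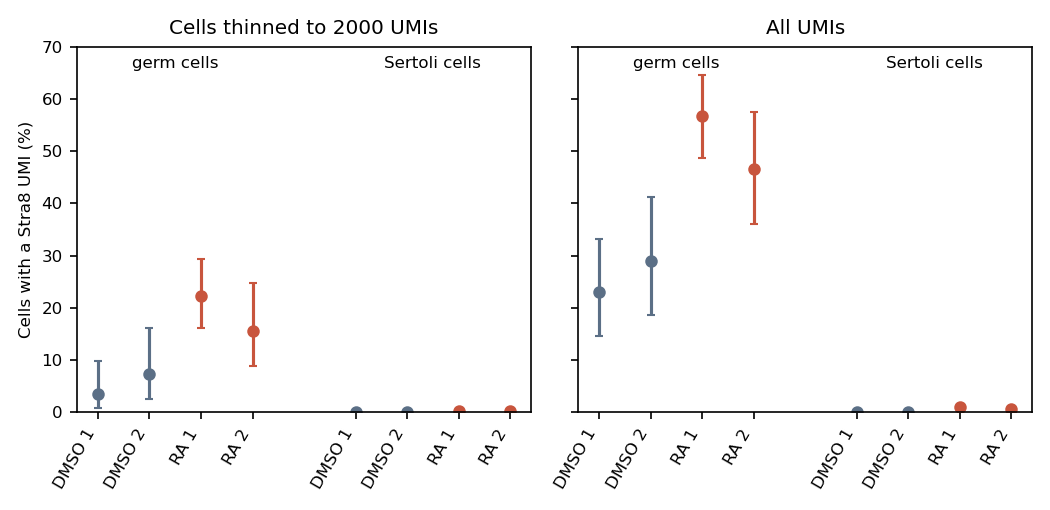
Share (%) of germ and Sertoli cells with at least 1 Stra8 UMI in each library, with exact 95% intervals, after thinning to 2000 UMIs per cell and with all UMIs. Thinned germ cell shares are 3.45 and 7.25% in the DMSO libraries and 22.2 and 15.6% in the RA libraries, and thinned Sertoli shares do not exceed 0.164%.

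Germ cells of the RA libraries with a Stra8 UMI after thinning (36 and 14 cells) were set against those without (126 and 76). Unthinned, 92 of the 162 and 42 of the 90 cells held a Stra8 UMI, so the group without is mixed. Of 1961 genes tested 2 were higher, Snap23, which encodes a membrane fusion protein (log2 difference 2.28), and Gpx1, a peroxidase that reduces hydrogen peroxide (1.50), and 32 were lower. The lower genes comprised 21 ribosomal protein genes, 5 mitochondrial genes and 6 others; those named by the rule were Rps15a (-0.66), mt-Nd4 (-0.69), Cox7a2l (-0.77), Rbm39 (-0.98) and Nsa2 (-1.14). No gene list passed camera (lowest adjusted p = 0.546), and without TMM scaling 6 genes passed, 2 higher and 4 lower. Among those lost were mt-Nd4 (adjusted p = 0.0562), Cox7a2l (0.0947), Nsa2 (0.107) and Rbm39 (0.146). The balance changed with the thinning: 34 genes were higher and 88 lower at 4000 UMIs, and 374 higher and 348 lower unthinned. Thinning also changed which cells counted as with Stra8 (46 and 26 at 4000 UMIs) and the number of genes tested (3400 at 4000 UMIs, 8721 unthinned). These were not separated. Gpx1 was at 0.75 and Snap23 did not pass at 4000 UMIs (0.84, adjusted p = 0.486), nor did Rbm39 (-0.11, adjusted p = 0.86), and mt-Nd4 did not unthinned (-0.17, adjusted p = 0.436). Unthinned, camera placed 3 lists higher in cells with Stra8: spermatogonial differentiation (adjusted p = 1.3e-05), S phase (2.21e-04) and undifferentiated spermatogonia (0.00504). Without thinning the depth of the cells was not made equal. At 4000 UMIs the same lists did not pass camera (adjusted p = 0.276, 0.726 and 0.219). The correlation was preset in these list tests, and no estimated correlation was run.

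Sertoli cells changed in 2564 of 13471 genes, 1404 higher and 1160 lower after RA. Genes of retinoid metabolism were among them. Cyp26a1, at 4 UMIs in both DMSO libraries together, rose to 114 ± 22.9 CPM and Cyp26b1 rose from 12.7 to 199 CPM (log2 change 3.97). Dhrs3 rose from 2.11 to 82.8 CPM (5.29 ± 0.17) and Rdh10, which makes retinaldehyde, from 8.70 to 140 CPM. The retinol transporter gene Stra6 rose from 10.2 to 30.1 CPM (1.56, adjusted p = 9.57e-04). Aldh1a1, an RA-synthesising dehydrogenase, fell from 459 to 163 CPM (-1.49, adjusted p = 3.05e-05). Rarb had 3 UMIs in the DMSO and 345 in the RA libraries, a ratio of 97.7 with a counting interval of 33.1 to 476. Stra8 had 0 and 49 UMIs, at least 13.9-fold higher (floor of 3 UMIs over the group; adjusted p = 0.0025). Other large rises were Tmem255a (6.36), Stbd1 (4.92) and Cidea, a lipid droplet protein gene (4.91 ± 0.18, 25.7 to 774 CPM). Uchl1, a ubiquitin hydrolase gene used as a spermatogonial marker (4.42 ± 0.17, 12.0 to 257 CPM), and Tgm2, a transglutaminase gene (4.05), rose as well. Large falls were Foxs1, a forkhead factor gene (-6.29, 82.4 to 1.05 CPM), Spata21 (-6.12, 29.0 to 0.41 CPM) and Emilin3 (30.9 to 1.95 CPM). They were followed by Dusp15 (-3.47), Rgcc (-3.39), Gldn (-3.28), Prrx2 (-3.21) and Tspan15 (-3.13). Foxs1 (ENSMUSG00000074676) is a protein-coding gene on chromosome 2, 152931898 to 152933208, minus strand, of GRCm38.

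Genes for 3 factors that Sertoli cells secrete or display fell. Gdnf, the growth factor of spermatogonial stem cells, fell from 20.9 to 9.77 CPM (-1.10, adjusted p = 5.26e-04), and Kitl, the ligand of Kit, from 112 to 73.4 CPM (-0.61, adjusted p = 0.00636). Amh, anti-Müllerian hormone, fell from 1227 to 658 ± 205 CPM (-0.90, adjusted p = 0.00883). Without DMSO replicate 2 the adjusted p of Kitl was 0.108. Crabp2, at 0.20 and 0.10 CPM, was too low to be tested. Without TMM scaling 64.6% of the genes that passed were higher after RA, against 54.8% with it. Without RA replicate 2 the number that passed was 4229. Free RNA was estimated at 2.37 to 3.17% of Sertoli UMIs.

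Of 22 retinoid response genes tested in Sertoli cells 12 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 1.59e-25, adjusted p = 0.129 with an estimated correlation). Of 15 genes of retinoid synthesis and turnover 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 2.87e-20, adjusted p = 0.129 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 20 cases (11 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.911 with an estimated correlation). Among them were Idi1 (0.74), Sc5d (0.70, 5.10 to 8.28 CPM) and Fdft1 (0.51, 23.7 to 33.9 CPM). Of 28 genes of G2 and M phase 5 rose (6 adjusted over the list alone, camera adjusted p = 0.0278, adjusted p = 0.911 with an estimated correlation), including Dlgap5, Cks2, Cenpf and Birc5. Of 28 S phase genes 1 fell. Of 20 growth factor and signalling genes 3 rose and 9 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.911 with an estimated correlation). Pdgfa fell from 197 to 51.2 CPM (-1.94) and Inha, the inhibin alpha subunit gene, from 2154 to 950 CPM (-1.18). Sertoli identity genes went both ways, 5 higher and 8 lower of 20 (7 and 9 adjusted over the list alone, camera adjusted p = 0.644). Sox9, a testis-determining factor gene, rose from 158 to 475 CPM (1.59). The gap junction gene Gja1 fell from 290 to 71.3 CPM (-2.02) and Cst9 and Clu fell from 935 to 309 and from 1546 to 654 CPM. The other lists did not pass camera in Sertoli cells, with 4 of 14 members higher and 4 lower for spermatogonial differentiation, 3 and 3 of 14 for steroidogenesis and 3 and 4 of 21 for glycolysis and hypoxia. Higher and lower members numbered 5 and 2 of 18 for apoptosis and p53, 5 and 5 of 24 for immediate early genes, 3 and 1 of 23 for collagens and matrix and 3 and 1 of 16 for the interferon response. They numbered 3 and 0 of 12 for smooth muscle contraction, 2 and 1 of 13 for meiotic prophase, 0 and 3 of 13 for undifferentiated spermatogonia, 2 and 1 of 6 for pluripotency, 1 and 1 of 7 for erythrocyte transcripts and 0 of 14 for DNA methylation.

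The class by treatment term tested whether germ and Sertoli cells responded differently. It passed for 948 of 15976 genes, with the response in germ cells higher for 435 and lower for 513 (2609 at an unadjusted p under 0.05). Of these genes, 436 had risen and 325 had fallen in Sertoli cells, and 181 had not passed there. In germ cells themselves, 8 of those that had risen in Sertoli cells and 2 of those that had not passed there were called. The rest were not called or not tested in germ cells. The p-values of this term are those of a normal curve at the fitted difference over its SE (Nell2, 4.60 and 1.33, unadjusted p = 5.55e-04). The spread of a single gene between pools of pups thus did not enter them, unlike in the tests within a class. The number that passed is therefore not on an equal footing with the numbers per class and may be too high. Uchl1 showed the most negative difference (-4.63): scaled over the germ and Sertoli sums together, its germ cell levels were 386 and 452 CPM after DMSO and 362 and 378 CPM after RA. Its Sertoli levels were 13.2 and 17.1 CPM after DMSO and 352 and 307 CPM after RA. Spata21 showed the most positive (6.04 ± 0.59), with a fall in Sertoli cells (-6.12). Its germ cell levels were 5.02 and 4.59 CPM after DMSO and 3.96 and 6.13 CPM after RA. Without DMSO replicate 1 the number was 473 and without RA replicate 1 it was 347.

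**Figure D3:**
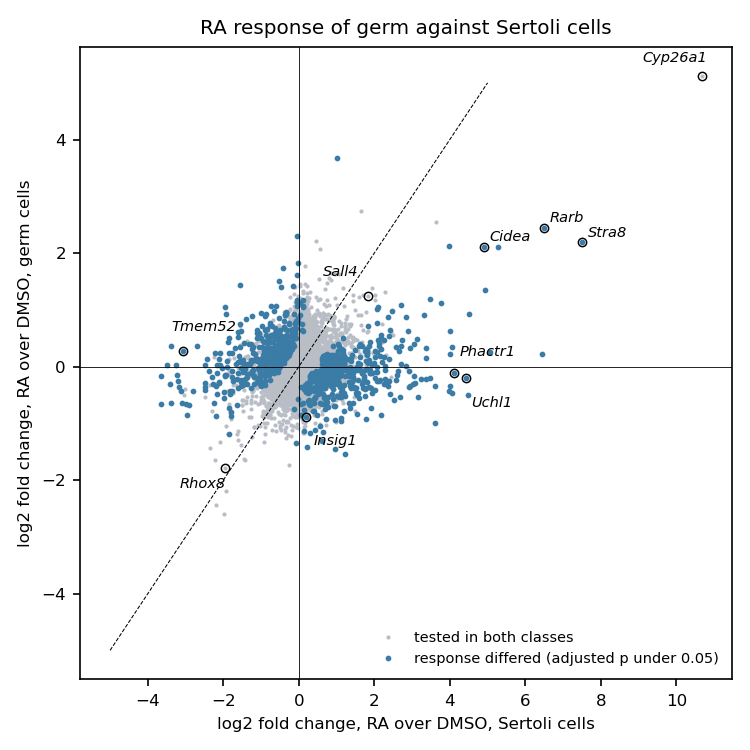
Fitted log2 fold change after RA in germ cells against that in Sertoli cells for the 9647 genes tested in both classes, with the 815 genes that passed the test of a different response marked and a dashed line where both are equal. Uchl1 lies far from the line, with 4.42 in Sertoli cells; fitted values of genes near 0 counts, such as Stra8, Cyp26a1 and Rarb in Sertoli cells, are not bounds.

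In peritubular myoid cells 403 genes rose and 246 fell of 11993. The largest rises were the long non-coding RNA gene Gm12840 (5.92, 2.07 to 125 CPM), Lrat, the enzyme that stores retinol as ester (5.52, 0.48 to 22.8 CPM), and Cyp2d22 (5.33). The largest falls were Crip1 (26.8 to 6.60 CPM), Anxa11 (-1.85, 154 to 43.0 CPM) and Cxcl14 (-1.83). Crip1 did not pass by markers (-0.12, adjusted p = 0.841) or with DESeq2 (0.0914), and leaving out each library gave -2.57 to -1.14. Dhrs3 (2.59, 34.3 to 206 CPM) and Rarb (4.48, 0.30 to 7.02 CPM) rose. Cyp26b1 stood at 47.4 and 72.2 CPM (0.60, adjusted p = 0.19), and passed without RA replicate 1 (0.95, adjusted p = 1.1e-06) and with no filter (0.00154). Of 14 smooth muscle contraction genes 6 rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.57e-08, adjusted p = 0.381 with an estimated correlation). Among them were Lmod1 (1.97, 5.30 to 20.7 CPM), Acta2 (0.97, 1169 to 2289 CPM), Cald1 and Myh11. Retinoid response genes rose in 6 of 25 cases (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.2e-07, adjusted p = 0.292 with an estimated correlation). Of 18 Sertoli identity genes 1 rose and 4 fell (Clu, Gja1, Cst9 and Amh; 1 and 5 adjusted over the list alone, camera adjusted p = 0.00671, adjusted p = 0.328 with an estimated correlation). Free RNA was 3.92 to 5.31% of myoid UMIs. Clu, Gja1, Cst9 and Amh fell in Sertoli cells too, and the change that free RNA alone would give was not computed for myoid cells. Cst9 and Amh are also in the set of Sertoli markers from which the free RNA of myoid cells was estimated. Their myoid levels were thus taken to be free RNA. Their falls are no evidence of a change in myoid cells, and the test of the Sertoli identity list includes both. The number of genes that passed was 384 without DMSO replicate 2 and 1383 without RA replicate 2.

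In interstitial stromal cells 460 genes rose and 271 fell of 13082. Gm12840 (7.10, 0.73 to 104 CPM), Lrat (6.52, 0.40 to 38.1 CPM) and Il33, an interleukin gene of stromal and epithelial cells (5.39, 0.84 to 36.0 CPM), rose most. Hbb-bt, a haemoglobin gene (-1.78, 36.7 to 10.9 CPM, adjusted p = 0.0311), Lrrn3 (-1.62) and Cst9, a Sertoli cell gene (21.0 to 6.99 CPM), fell most. Hbb-bt did not pass with DESeq2 (adjusted p = 0.324), without TMM scaling (0.0638), at 10 CPM (0.0518), by markers (0.0664) or with free RNA subtracted (0.135). Its log2 change was -2.78 without RA replicate 2 and -1.15 without RA replicate 1. Haemoglobin RNA in stromal cells was 563, 260, 76.2 and 308 CPM in DMSO 1, DMSO 2, RA 1 and RA 2. Dhrs3 (3.07, 27.6 to 232 CPM), Rarb (4.71, 0.40 to 10.9 CPM) and Cyp26b1 (0.84, 74.6 to 134 CPM, adjusted p = 0.0337) rose as well. The adjusted p of Cyp26b1 was 0.0718 without DMSO replicate 1, 0.247 with DESeq2, 0.0528 at 10 CPM and 0.0551 as deposited. Of 26 retinoid response genes 9 rose (10 rose and 3 fell adjusted over the list alone, camera adjusted p = 1.54e-14, adjusted p = 0.241 with an estimated correlation). Of 28 S phase genes Hells and Ccne2 rose (8 adjusted over the list alone, camera adjusted p = 2.13e-04, adjusted p = 0.75 with an estimated correlation). Of 28 genes of G2 and M phase Hjurp and Nuf2 rose (9 adjusted over the list alone, camera adjusted p = 4.4e-06, adjusted p = 0.75 with an estimated correlation). Without TMM scaling 74.0% of the genes that passed were higher, against 62.9% with it. Without RA replicate 2 the number that passed was 1496. Free RNA was 3.86 to 4.91% of stromal UMIs. Cst9 fell in Sertoli cells too, and the change that free RNA alone would give was not computed for stromal cells. Cst9 is also in the set of Sertoli markers from which the free RNA of stromal cells was estimated. Its stromal level was thus taken to be free RNA, and its fall is no evidence of a change in stromal cells.

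Endothelial cells (63 and 65 cells after DMSO, 51 and 82 after RA) changed in 103 of 5972 genes, 63 higher and 40 lower. Cyp26b1 had 1 UMI in the DMSO and 940 in the RA libraries (1.14 to 781 CPM), a ratio of 724 with a counting interval of 130 to 28600. Tcf15, a transcription factor gene, rose from 35.3 to 503 CPM (3.84), Nr0b1 from 3 to 85 UMIs (ratio 21.8, counting interval 7.22 to 108) and Dhrs3 from 9.69 to 91.3 CPM (3.19). By markers the log2 change of Cyp26b1 was 2.52 (adjusted p = 1.07e-06). Ctgf, a matrix-associated growth factor gene, fell from 125 to 18.3 CPM (-2.69; -1.09 by markers), Ift122 from 41.2 to 8.87 CPM (-2.14, adjusted p = 0.0289) and Celsr1 from 40.1 to 10.6 CPM (adjusted p = 0.0489). The falls of Ift122 and Celsr1 did not pass without DMSO replicate 1 (adjusted p = 0.0911 and 0.12), DMSO replicate 2 (0.385 and 0.459) or RA replicate 1 (0.0601 and 0.135), or with free RNA subtracted (0.0526 and 0.0824). Ift122 also did not pass by markers (-0.50, adjusted p = 0.498), nor Celsr1 without TMM scaling (0.0654) or with no doublets removed (0.0538). Of 13 retinoid response genes 7 rose (7 rose and 2 fell adjusted over the list alone, camera adjusted p = 6.34e-21, adjusted p = 0.137 with an estimated correlation). Tgm2 was among them (2.30, 59.0 to 291 CPM). The number of genes was 61 without DMSO replicate 1, 40 without DMSO replicate 2 and 275 without RA replicate 2, where 109 were higher and 166 lower. Without TMM scaling 76.6% were higher, against 61.2% with it. Free RNA was 3.42 and 2.84% of endothelial UMIs after DMSO and 7.44 and 3.57% after RA.

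Macrophages (39, 28, 45 and 49 cells) changed in 63 of 4672 genes, 44 higher and 19 lower. Cd38, an NAD-consuming ectoenzyme gene, rose from 5.84 to 261 CPM (5.35), and the chemokine genes Ccl9 and Ccl6 from 19.3 to 417 and from 38.6 to 800 CPM. Stfa1 (312 ± 373 to 28 CPM, adjusted p = 0.0431), the proliferation gene Top2a (-2.43, adjusted p = 0.0494) and S100a8 (-2.40, 911 to 174 CPM, adjusted p = 0.0106) fell most. Without DMSO replicate 1 the adjusted p was 0.716 for Stfa1 and 0.66 for Top2a, and the log2 change of S100a8 was -1.43. With no doublets removed the adjusted p was 0.496 for Stfa1, 0.933 for Top2a and 0.395 for S100a8, and at 10 CPM it was 0.147, 0.122 and 0.07. Stfa1 also failed with DESeq2 (0.513), no filter (0.135), as deposited (0.0584) and with free RNA subtracted (0.0658). Top2a failed with no filter (0.142), as deposited (0.145) and by markers (0.902), and S100a8 with DESeq2 (0.361) and by markers (0.269). Summed neutrophil markers, S100a8 and Stfa1 among them, stood at 1920, 499, 294 and 103 CPM in the macrophage class of DMSO 1, DMSO 2, RA 1 and RA 2. Of 6 genes of G2 and M phase 1 fell (5 adjusted over the list alone, camera adjusted p = 1.13e-05, adjusted p = 0.588 with an estimated correlation). Dhrs3 rose from 103 to 232 CPM (1.17, adjusted p = 0.0411). It did not pass with DESeq2 (0.119), no filter (0.125), at 10 CPM (0.116), with no doublets removed (0.0565), as deposited (0.051), by markers (0.0574), with free RNA subtracted (0.0801) or without RA replicate 2 (0.122). Leaving out DMSO 1, DMSO 2, RA 1 or RA 2 gave 125, 142, 133 and 170 genes, with 67 higher and 75 lower without DMSO 2, and free RNA was 6.86, 8.84, 6.55 and 11.3% of macrophage UMIs.

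In fetal-type Leydig cells, the steroid-producing cells (53, 70, 90 and 62 cells), 1 of 6952 genes passed, the kinase gene Itpkb (49.2 to 194 CPM, log2 change 1.99 ± 0.23, adjusted p = 0.0161; 0.109 without RA replicate 1). Star, which carries cholesterol into mitochondria, stood at 171 and 147 CPM (adjusted p = 0.943), Cyp17a1, a steroid hydroxylase gene, at 1806 and 2029 CPM (0.923) and Insl3, the hormone of testis descent, at 1695 and 1247 CPM (0.82). For Cyp17a1 the alternatives passed in opposite directions, with a log2 change of 0.70 in all barcodes as deposited (adjusted p = 0.00287) and -0.79 in Leydig cells assigned by markers (adjusted p = 0.00963). Of 12 retinoid response genes none passed (2 rose adjusted over the list alone, camera adjusted p = 0.00183, adjusted p = 0.533 with an estimated correlation), with Dhrs3 at 55.8 and 118 CPM (adjusted p = 0.392). At an unadjusted p under 0.05 there were 480 genes, and DESeq2 passed 2. With barcodes as deposited, apart from doublets (233, 234, 286 and 272 Leydig cells), 347 passed, 163 higher and 184 lower. That set was clustered anew without the limits on genes and mitochondrial UMIs. The main Leydig values therefore cover only the smaller part of the class that passed these limits, and the few genes that passed there do not show a weak response of Leydig cells. Leaving out DMSO 1, DMSO 2, RA 1 or RA 2 gave 59, 11, 4 and 66 genes.

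Over all cells together 982 genes rose and 719 fell of 16276. Without RA replicate 1 the number that passed was 825. Cyp26a1 (10.35, 0.04 to 58.6 CPM), Gm12840 (1.38 to 59.0 CPM) and Cidea (4.79, 14.2 to 393 CPM) rose most. The neutrophil gene Ngp (44.9 to 4.32 CPM, adjusted p = 0.0186), Rgcc (-3.07) and Scara5 (-2.96) fell most. Ngp did not pass with DESeq2 (adjusted p = 0.176), without TMM scaling (0.0737) or at 10 CPM (0.0546), and its log2 change was -6.50 without RA replicate 1 and -2.46 without RA replicate 2. Smooth muscle contraction genes rose in 5 of 15 cases (9 adjusted over the list alone, camera adjusted p = 5.26e-04, adjusted p = 0.872 with an estimated correlation). Erythrocyte transcripts fell in 4 of 9 cases and rose in 1 (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.63e-04, adjusted p = 0.872 with an estimated correlation).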

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

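No test in this part was chosen after the result was seen. The 948 genes whose response to RA differed between germ and Sertoli cells were taken up because 2 classes of the same libraries differed under the same contrast, by the class by treatment term itself. The 5 most positive differences, as log2 response in germ cells minus that in Sertoli cells, were Spata21 (6.04), Nell2 (4.60), Foxs1 (3.75), Tmem206 (3.42) and Tmem52 (3.37). The 5 most negative were Uchl1 (-4.63), Insc (-4.61), Lzts1 (-4.59), Cytip (-4.42) and Phactr1 (-4.16). The p-values of this term leave out the spread of a single gene between pools of pups, as given above. A positive difference need not be a rise in germ cells. Spata21, Foxs1, Tmem206 and Tmem52 fell in Sertoli cells (-6.12, -6.29, -2.71 and -3.08). Several of the named differences rest on counts near 0 in 1 class, where the fitted size is no bound. Nell2 stood at 0.39 and 0.08 CPM in Sertoli cells of the DMSO libraries and at 0 in those of the RA libraries. Foxs1 stood at 0.61 and 0.56 CPM in germ cells of the RA libraries. Without DMSO replicate 1, RA replicate 1 or RA replicate 2 the adjusted p was 0.399, 0.211 and 0.13 for Nell2 and 0.144, 0.618 and 0.106 for Foxs1; without DMSO replicate 1, DMSO replicate 2 or RA replicate 1 it was 0.139, 0.0977 and 0.117 for Cytip; and without DMSO replicate 1 it was 0.171 for Insc. Uchl1, a spermatogonial marker gene, reached in Sertoli cells of the RA libraries (352 and 307 CPM) a level close to that of germ cells (362 and 378 CPM).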

How the results depend on the processing

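The subtraction of free RNA was chosen after the result was seen; the other settings were not. Of 78 named genes that passed, 52 passed in the same direction under every alternative run for them. An alternative whose filter left a gene untested was skipped for that gene and not counted against it, so the 52 are an upper limit. Over all values of these 78 genes under alternatives, 973 kept direction and side of the threshold and 88 kept direction without passing, and none turned. For named genes that had not passed, 182 values stayed so, 19 passed in the same direction and 22 turned; for gene lists that passed, 408 values passed in the same direction, 126 kept direction without passing and 5 turned. Where 1 library was left out, the lone library of that group was assumed to vary like the others. Germ, Leydig, endothelial and macrophage classes held 28 to 162 cells per library; in simulated data 46.3% of 2-fold changes were recovered in germ cells and 85.1% in Sertoli cells, and the other small classes were not simulated. The filter at 10 CPM tested 8179 genes against 16276 in all cells, 7825 against 13471 in Sertoli and 7817 against 13082 in stromal cells, and more in macrophages (7579 against 4672); for all changes below the cause was not tested.

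Numbers of genes changed by RA were, with DESeq2, 4 in germ cells, 2 in Leydig cells, 46 in endothelial cells and 34 in macrophages; without TMM scaling 46 in germ and 2 in Leydig cells; and with no filter on low counts 57 in germ cells, 62 in Leydig, 1267 in myoid, 1553 in stromal, 197 in endothelial cells and 33 in macrophages. At 10 CPM or more in 2 libraries they were 924 in all cells, 1599 in Sertoli cells, 445 in stromal cells and 33 in macrophages. With no doublets removed 15 genes passed in Leydig cells; with barcodes as deposited 50 in germ and 347 in Leydig cells; with classes by markers 43 in germ, 700 in Leydig and 244 in endothelial cells; and with free RNA subtracted 7 in germ, 2 in Leydig and 65 in endothelial cells. With a replicate block, which assumes that equal numbers share a source, they were 4288 in all cells, 138 in germ (59 higher and 79 lower), 4683 in Sertoli, 39 in Leydig, 1421 in myoid, 1357 in stromal cells and 23 in macrophages; the correlation across genes of residuals of equally numbered libraries was 0.016 to 0.28 by class (0.123 in germ cells). Among named genes, the block put Dhrs3 (adjusted p = 0.00245) and Ccnd2 (1.59e-04) in germ cells and Cyp26b1 in myoid cells (0.00514) past the threshold, and Celsr1 in endothelial cells (0.0666), Top2a (0.0749) and Dhrs3 (0.0864) in macrophages and Foxs1 in germ against Sertoli cells (0.0544) outside it.

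Leaving out each library gave 825 to 2240 genes in all cells, 9 to 106 in germ, 1773 to 4229 in Sertoli, 4 to 66 in Leydig, 384 to 1383 in myoid, 686 to 1496 in stromal, 40 to 275 in endothelial cells and 125 to 170 in macrophages, and 347 to 785 genes with a different response in germ and Sertoli cells. Germ cells with and without Stra8 differed in 122 genes at 4000 UMIs, 722 unthinned and 6 without TMM scaling, and Rbm39 turned to 0.11 unthinned. The difference in the share of germ cells with Stra8 was 9.97 points at 1000 UMIs, 22.9 points at 4000 UMIs and 25.7 points unthinned; it was 10.3 points with no doublets removed, where the DMSO mean was 10.7% against 5.35%, and 14.9 points by markers, and leaving out each library gave 10.2 to 16.9 points. The number of lists that passed, 45, was 0 with an estimated correlation and 8 by fry.

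The number of class shares that passed, 0, was 1 with no doublets removed, at resolution 2, with a replicate block and without RA replicate 2 (erythroid cells in each), and 1 by markers (Schwann or neural cells); leaving out each library gave 0 to 1. The log2 change of a share turned for Leydig cells (-0.008 as deposited), myoid cells (-0.028 as deposited, -0.14 at resolution 2), stromal cells (-0.059 by markers) and endothelial cells (0.15 by markers), and moved from 0.054 to 0.92 for myoid cells by markers. Leydig shares were 3.41, 3.05, 3.18 and 3.24% as deposited and 2.10, 1.44, 2.60 and 3.52% by markers, in the order DMSO 1, DMSO 2, RA 1 and RA 2. Leaving out each library it ranged from -0.005 to 0.72 for germ cells, -0.19 to 0.22 for Leydig cells, -0.66 to 0.15 for endothelial cells and -0.084 to 0.56 for macrophages. Among germ cell genes that had not passed, Dnmt3b turned to 0.092 without TMM scaling, 0.005 with no filter, 0.29 as deposited and 0.01 by markers, and Pou5f1 to 0.019 without TMM scaling, 0.02 as deposited and 0.004 by markers. Leaving out each library gave log2 changes of -0.66 to 0.24 for Kit, -0.27 to 0.41 for Dnmt3b, -0.11 to 0.56 for Id4, -0.12 to 0.73 for Ret and -0.28 to 0.18 for Pou5f1. In Leydig cells Star turned to 0.43 as deposited and Cyp17a1 to -0.79 by markers, and leaving out each library gave -0.72 to 0.59 for Star, -0.20 to 0.46 for Cyp17a1 and -0.89 to 0.20 for Insl3. Leydig lists turned for G2 and M phase (adjusted p = 0.00451 as deposited), Sertoli identity (0.876 with no doublets removed) and erythrocyte transcripts (0.175 as deposited). Leaving out each library the adjusted p of G2 and M phase was 2.3e-22 to 0.633 and that of erythrocyte transcripts 9.32e-119 to 0.0725, with the direction turned without RA replicate 1 for the former (6.39e-04) and without RA replicate 2 for the latter (3.38e-07).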

Other observations

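The 2 tests of RNA from other cells in the germ cell sums, the subtraction of free RNA, and the marker sums of haemoglobin and neutrophil RNA, were chosen after the result was seen; the 4 tests concerning Stra8 were not. In Sertoli cells, genes of several other groups moved in both directions. Hsd17b3, which reduces androstenedione to testosterone, fell from 304 to 113 CPM (log2 change -1.43, adjusted p = 0.00147), Fdxr, a mitochondrial electron donor for steroid synthesis, from 223 to 65.9 CPM (-1.76) and Akr1b7 from 26.4 to 8.52 CPM (-1.63), while Por, the electron donor of microsomal P450 enzymes, rose from 16.6 to 30.8 CPM (0.89). The heat shock gene Hspb1 fell from 760 to 372 CPM (-1.03) and the orphan receptor gene Nr4a1 from 63.4 to 18.8 CPM, and the immediate early genes Ier3 and Klf6 rose (1.57 and 1.06). Among genes of stress and survival Gadd45b rose from 20.6 to 69.0 CPM (1.74), Sesn2 and Bcl2l1 rose (1.09 and 0.84) and Phlda3 fell (-0.83), and among genes of glycolysis and hypoxia Adm, the adrenomedullin gene, rose from 0.26 to 6.53 CPM (4.63) and Pfkl rose (1.62), while Ankrd37 (-1.66) and Aldoa (-0.62) fell.

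In endothelial cells 1 of 19 immediate early genes fell, Ier2 (-0.77, 496 to 292 CPM), and 8 fell adjusted over the list alone (camera adjusted p = 1.04e-04; adjusted p = 0.436 with an estimated correlation), while in myoid cells 3 of 23 rose (5 adjusted over the list alone; camera adjusted p = 0.0126; adjusted p = 0.328 with an estimated correlation); the difference between the 2 classes was not tested. In macrophages the stromal matrix gene Dcn rose from 43.0 to 178 ± 119 CPM (adjusted p = 0.0465) and the smooth muscle gene Acta2 from 17.6 to 67.5 CPM (adjusted p = 0.0431), in a class with 6.86, 8.84, 6.55 and 11.3% free RNA. In Leydig cells 3 of 4 erythrocyte transcripts rose adjusted over the list alone and none over all genes (camera adjusted p = 0.0117; adjusted p = 0.773 with an estimated correlation), with haemoglobin RNA at 135, 244, 62.4 and 5085 CPM in DMSO 1, DMSO 2, RA 1 and RA 2; without RA replicate 2 the list was lower after RA (adjusted p = 3.38e-07). Neutrophil marker RNA over all cells was 263, 535, 212 and 41.6 CPM in the same order.

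The genes that passed in germ cells were set against RNA from other cells, taken as the estimated share of such RNA times the change over the whole library. In the median of the 15 genes that rose the predicted change was 46.9% of the observed one (bootstrap 95% interval 0.6 to 87.6%). In the median of the 7 that fell it was 52.2% (0.7 to 91.2%). Both sets were mixed. Of the 15 rises, 6 had a predicted share of 0.5 or more of the observed change and 6 of 0.25 or less. Of the 7 falls these were 4 and 2. The share was 93.7% for Cidea, 94.9% for Fstl3, 93.5% for Id3 and 150.8% for Rhox8. It was 0.3% for Hoxb4, Stra8 and Sall4 and 2.2% for Rarb. With intervals this wide, RNA from other cells and a response of the germ cells to RA cannot be told apart for either set as a whole. With free RNA subtracted 7 of the 22 genes passed, among them Stra8 (log2 change 2.19 ± 0.27 before and 2.21 ± 0.29 after), Hoxb4 (2.05 ± 0.25 and 2.07 ± 0.25), Sall4 (1.25 ± 0.18 and 1.27 ± 0.18) and Rarb (2.44 ± 0.36 and 2.43 ± 0.37), which argues against free RNA, as estimated here, as the whole source for these 7. Cpm (1.08 ± 0.23 and 1.10 ± 0.23) and 2810474O19Rik (0.90 ± 0.17 and 0.88 ± 0.18), named after their values were seen, lost the call (adjusted p = 0.13 and 0.0821) with fold and SE nearly unchanged and a predicted change of 0.6 and 12.8% of the observed one, so the lost calls do not speak for free RNA, and the source stays open for them. For the 7 a response of the germ cells to RA is a hypothesis that other technical causes were not tested against.

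Stra8 UMIs also appeared in Sertoli cells of the RA libraries, 33 and 16 against 0 in the DMSO libraries. Droplets holding a germ and a Sertoli cell are argued against: 10.87% of the 46 Sertoli cells with Stra8 (interval 3.62 to 23.57%) held a UMI of 8 germ cell markers, against 8.84% of those without and 100% of germ cells. Free RNA of germ cells would keep Stra8 in 1 ratio to Ddx4 and Dazl; the ratio in Sertoli cells over that in germ cells was 2.62 (1.47 to 4.64) in RA replicate 2 and 3.18 (2.08 to 4.87) in RA replicate 1, with 10.4 and 6.1 UMIs predicted in RA 1 and RA 2. The lower bound was under the limit of 2, set in advance, in RA replicate 2. The ratio therefore cannot tell apart free RNA and Stra8 transcription in Sertoli cells after RA. At 0.89 and 0.45 CPM in RA 1 and RA 2, Stra8 in Sertoli cells was not tested with the filter at 10 CPM. Its call held under every alternative run for it, the subtraction of free RNA among them. That subtraction used a share taken from stromal markers, which RNA of germ cells need not follow. Stra8 UMIs in the other somatic classes of the RA libraries were 12 and 5 in stromal, 7 and 2 in myoid and 2 and 0 in Leydig cells.

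The 32 genes that were lower in germ cells with a Stra8 UMI, 21 of them ribosomal protein and 5 mitochondrial genes, had a median log2 difference of -0.40 and -0.36 in RA 1 and RA 2. Cell depth as the source took cells with a Stra8 UMI to be deeper before thinning. Their median was 13544 UMIs against 15672 without in RA 1, where this was not so, and 16842 against 16470 in RA 2. In germ cells without a Stra8 UMI after thinning, the same genes differed by 0.048 (RA 1) and 0.137 (RA 2) between deep and shallow cells (mean 0.092). In RA 1, where cells with Stra8 were shallower, this goes the same way as the lower genes. The sizes, small beside -0.40 and -0.36, argue against cell depth as the source. The group without a Stra8 UMI is mixed, since 92 of the 162 and 42 of the 90 germ cells held a Stra8 UMI before thinning. Free RNA may differ between the groups, since Sertoli markers differed by -1.11 on the log2 scale between cells with and without Stra8, but that rests on 8 and 4 UMIs against 69 and 41, too few to decide, so free RNA and a difference among germ cells that respond to RA cannot be told apart.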
